A study of Mus musculus with 20 samples.

How the data were processed

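RNA was sequenced from 20 samples of mouse bone marrow-derived macrophages in 6 groups: control siRNA with vehicle (n = 3), LPS (n = 3) or Dex+LPS (n = 4), and Brg1 siRNA with the same treatments (n = 3, 3 and 4). Per the labels' protocols, marrow cells of male C57BL/6J mice were purified on Ficoll and differentiated for 7 days in medium with L929 supernatant. They were transfected with 50 nM siRNA, 1 product per arm, for 48 h, and treated during the last 6 h. The labels' protocols name a stranded mRNA library kit with 500 ng of RNA as input and also speak of rRNA depletion, so it is open whether polyadenylated RNA was selected. They do not say which strand was counted, or whether replicates are separate animals or separate cultures, so the p-values measure only the spread between these samples. The series' design text speaks of 3 replicates, and the labels give 4 in each Dex+LPS group. All 20 labelled samples were used.

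The authors deposited a single table of 17787 genes with 20 columns of normalized signal, whose headers name a DESeq normalization. That the values are gene counts divided by a size factor per library was inferred from the values themselves, as given below. The table also holds log2 fold changes with standard errors, p-values and adjusted p-values for 7 comparisons, computed by the authors. Per the submitters' processing notes the tools were Salmon 1.4.0, DESeq, DESeq2 and R 4.1.0, with the builds mm10 and GRCm38.p6. Whole read numbers were recovered from the signal columns as multiples of the smallest step in each library: 99.95% of the values above 0 lay within 0.01 of a whole number and 100% within 0.06. Library depths summed from these reads were 13.69 to 18.71 M. Size factors recomputed from the reads differed from those in the deposited signal by at most 0.0974%. Counting intervals and floors (3 reads over a group) cover counting error only.

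The test was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), with all 6 groups in a single fit and Benjamini-Hochberg adjustment within each comparison at an adjusted p under 0.05. Genes with a normalized count of at least 10 in at least 3 samples were kept, 12061 in all. The test for normalized values, the gene lists, the rule for named genes and the alternatives not listed below as added were fixed before the data were examined. The filter was set once the unit was known, since the plan named a filter for counts. The plan named an edgeR test for counts and limma for normalized values, and the deposited unit led to limma. The edgeR and DESeq2 tests on the recovered reads were run as alternatives (edgeR 4.0.16, DESeq2 1.42.0). With edgeR and TMM factors, 2503, 3868 and 4156 genes were called for the knockdown in vehicle, LPS and Dex+LPS. The 9 comparisons were not all independent, because the LPS and the Dex responses of an siRNA share their LPS libraries. They were the knockdown effect in each treatment, the LPS response (LPS against vehicle) and the Dex response (Dex+LPS against LPS) with each siRNA, and the difference of the knockdown effect between LPS and vehicle and between Dex+LPS and LPS.

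The pipeline was tested on simulated counts drawn with the means of the control siRNA groups, the spread between samples estimated from the reads and the real size factors, with 200 changed genes among 12061. For the knockdown in vehicle, 74.6% of the genes changed by 1 on the log2 scale and 93.9% of those changed by 2 were recovered, with 8.55% false calls. At a change of 1, recovery was 88.1% for the knockdown in LPS, 83.6% in Dex+LPS, 59.7% for the LPS interaction and 64.2% for the Dex interaction. False calls in these were 9.43%, 7.41%, 7.08% and 7.38% of the calls. All 5 shares lie above the 5% that the threshold aims at, so calls near the threshold may hold more false ones than it states. Each share comes from a single simulated data set with 200 changed genes, while the same real comparisons called 3.97% to 34.3% of the genes. The false share among the real calls is therefore not known, and the LPS and Dex responses were not simulated.

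The 24 gene lists were BAF complex subunits, primary and secondary LPS response genes, interferon-stimulated genes, glucocorticoid-induced genes, cholesterol synthesis, LXR targets and efflux, cell cycle, p53 targets, unfolded protein response and ATF4 targets, MHC class II and costimulation, alternative activation, macrophage identity, oxidative phosphorylation, glycolysis, markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells and basophils, erythroid cells and fibroblasts, mitochondrial transcripts, and non-polyadenylated and nuclear RNA. Lists with at least 5 tested genes were tested with camera of limma on log2(normalized count + 1), where the plan named log2 counts per unit of depth, at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Member counts are given over all genes tested and adjusted over the list alone. The lists were compared as primary against secondary LPS response genes by a two-sided permutation test with 100000 resamples across genes.

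Named genes were, per comparison, Smarca4, the 6 largest rises and 6 largest falls among genes with a mean normalized count of at least 100, an ordinary gene symbol and groups whose samples do not overlap, up to 3 members of each described list with the smallest adjusted p, and Tnf, Il1b, Il6, Il12b, Nos2, Ccl5, Tsc22d3, Fkbp5, Dusp1 and Per1 whatever their values. Cd163, also in that set, was not analysed here. Chance alone leaves 10% of genes without overlap for groups of 3 against 3, 5.71% for 3 against 4 and 2.86% for 4 against 4. All 17787 identifiers matched the GENCODE M21 annotation of GRCm38, which gave positions, overlaps and the share of each gene's 31-base words found in transcripts of another gene.

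Alternatives were DESeq2, edgeR with 2 normalizations, limma-voom, the authors' own columns, pseudocounts of 0.1 and 5, no filter on low values, plain library totals in place of size factors, the replicate number as a block, the library number series as a term or left out, fits with only the groups compared, stricter thresholds, and each library left out in turn. The library numbers in the labels fall into a 136 and a 181 series. The edgeR test with TMM factors, the authors' columns, a run without genes that switch within a group and plain library totals, the last planned only for the Smarca4 level, were added after seeing the data. What plain library totals would show for the interferon pattern was written before they were run. A like test for the cell cycle pattern was dropped, since that scaling moves all knockdown effects down and so could not have gone against it. Its place was taken by the list's mean log2 level less the median of all tested genes in each library, chosen after the results were seen. A split of the LPS libraries between the LPS and the Dex response, 1 against 2, was added last. Genes outside the deposited table were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.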

Results

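Transcript levels were measured by RNA sequencing in bone marrow-derived macrophages that had received control siRNA or siRNA against Brg1, the ATPase of the BAF chromatin remodelling complex, which the gene Smarca4 encodes. After 48 h of silencing, with vehicle, lipopolysaccharide (LPS, a bacterial cell wall component that macrophages sense through a Toll-like receptor, at 100 ng/ml) or LPS with 1 µM dexamethasone (Dex, a synthetic glucocorticoid) for the last 6 h, 20 libraries were made. There were 3 per siRNA with vehicle, 3 with LPS and 4 with Dex+LPS. Depth ran from 13.69 M reads (control siRNA, vehicle replicate 3) to 18.71 M (control siRNA, Dex+LPS replicate 4). With control siRNA, the other vehicle libraries held 14.34 and 14.44 M reads, the LPS libraries 15.86, 15.68 and 16.61 M, and the other Dex+LPS libraries 16.12, 13.85 and 14.36 M. With Brg1 siRNA, vehicle libraries held 15.5, 15.68 and 14.45 M reads, LPS libraries 15.99, 15.43 and 17.64 M, and Dex+LPS libraries 13.86, 14.06, 14.68 and 16.74 M. Values below are mean normalized counts ± SD, with n = 3 for vehicle and LPS groups and n = 4 for Dex+LPS groups. A list's counts are of genes called higher and lower. Samples of the compared groups do not overlap in any gene named below as among the largest rises or falls between 2 groups, where chance alone leaves 10%, 5.71% or 2.86% of genes so for 3 against 3, 3 against 4 or 4 against 4 samples.

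Smarca4 (ENSMUSG00000032187, chromosome 9, 21616169 to 21704230 in GRCm38) was lower in every library with Brg1 siRNA than in every library with control siRNA of the same treatment. Its normalized counts were 1476, 1538 and 1626 with control siRNA and vehicle against 365, 358 and 340.2 with Brg1 siRNA. With LPS they were 2989.8, 2899 and 2751 against 621, 559.5 and 600.1. With Dex+LPS they were 2032, 1745, 1905 and 2181 against 459.9, 414, 442 and 518. The log2 fold change was -2.12 (SE 0.085) in vehicle, -2.28 (SE 0.085) in LPS and -2.10 (SE 0.074) in Dex+LPS, with limma adjusted p = 1.5e-11, 3.76e-12 and 1.31e-12. The interaction test called no difference in the size of the knockdown between treatments (limma adjusted p = 0.477 between LPS and vehicle and 0.486 between Dex+LPS and LPS). Of the 23 tested BAF subunit genes, 2 were lower and 0 higher with Brg1 siRNA in vehicle, over all genes and adjusted over the list alone: Smarca4 itself and Actl6a, which fell by 0.31 on the log2 scale. In LPS 4 were higher and 2 lower (3 and 2 adjusted over the list alone), and in Dex+LPS 4 and 1 (1 and 1 adjusted over the list alone). Named after their values were seen, these were Arid1b, Arid2, Bcl7b and Bcl7c higher and Smarca4 and Smarcc1 lower in LPS, and Arid1a, Arid2, Dpf2 and Smarcc2 higher and Smarca4 lower in Dex+LPS.

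**Figure D1:**
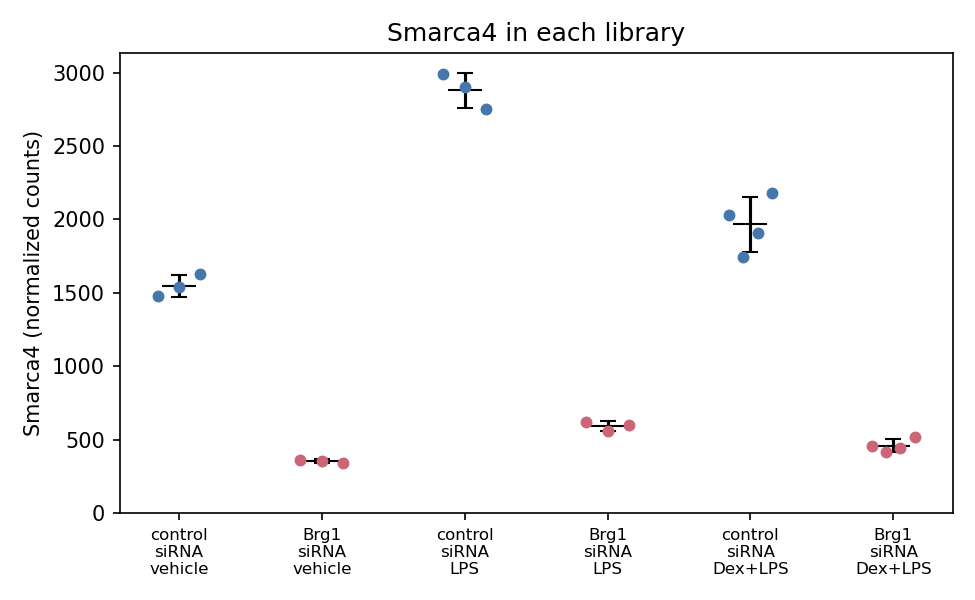
Normalized counts of Smarca4 per library (points) in the 6 groups, with the mean and SD as bars. The highest library with Brg1 siRNA, 621 in LPS, lies below the lowest with control siRNA, 1476 in vehicle.

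The knockdown in vehicle asks which transcripts depend on Brg1 in unstimulated macrophages. Interferon-stimulated genes rose with Brg1 siRNA: 27 of 35 tested were higher and 0 lower. Adjusted over the list alone these were 31 and 0. Rsad2 (viperin, an antiviral enzyme) went from 1705 ± 231 (SD, n = 3) to 4444 ± 258 (SD, n = 3), Zbp1 (a nucleic acid sensor) from 780.1 ± 87.6 to 1803 ± 112 and Gbp2 (a guanylate-binding GTPase) from 503 ± 67.3 to 1087 ± 93.0. Cell cycle genes fell, with 29 of 38 lower and 0 higher (33 and 0 adjusted over the list alone). Top2a (topoisomerase of dividing cells) went from 1357 ± 44.7 to 676 ± 70.7, Mki67 from 1344 ± 133 to 692 ± 36.0 and the spindle gene Nusap1 from 302 ± 11.2 to 142 ± 14.4. Cholesterol synthesis genes were lower in 10 of 25 and higher in 0 (13 and 0 adjusted over the list alone). They included Sqle (815 ± 29.7 to 510.1 ± 39.5) and Insig1 (778 ± 17.7 to 607 ± 40.0). Camera of limma gave adjusted p = 1.56e-20 for the interferon list (0.0772 with an estimated correlation), 3.32e-16 for cell cycle (0.00282). It was 0.000368 for cholesterol synthesis (adjusted p = 0.0667 with an estimated correlation). Mitochondrial transcripts made up 1.94%, 2.22% and 2.13% of the counts with control siRNA and 1.53%, 1.55% and 1.69% with Brg1 siRNA. Of 13 tested, 1 was lower (0 adjusted over the list alone), with camera adjusted p = 0.0265, and adjusted p = 0.506 with an estimated correlation. In Dex+LPS, where camera did not call the list (adjusted p = 0.0746), they made up 1.64%, 1.85%, 1.89% and 1.25% with control siRNA and 1.38%, 1.44%, 1.38% and 0.969% with Brg1 siRNA.

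Among single genes in vehicle, the basement membrane collagens Col4a1 and Col4a2 were among the largest falls. They lie head to head on chromosome 8 (Col4a1 11198423 to 11312826, Col4a2 11312805 to 11449287 in GRCm38). Col4a2 went from 235 ± 52.0 to 9.73 ± 0.446, while Col4a1 read 198, 187 and 142 with control siRNA and 0, 0 and 6.82 with Brg1 siRNA. The chemokine receptor Ccr3 fell from 584 ± 63.8 to 38.2 ± 4.57 (log2 fold change -3.90, SE 0.271, limma adjusted p = 1.56e-08). Slc6a4, the serotonin transporter, and Rasgrf1 rested on 2 reads each with Brg1 siRNA, a ratio of 52.9 (95% counting interval 14.1 to 422) and of 37.1 (10.4 to 309). Rises were led by the chemokine Ccl5 (57.6 ± 5.96 to 286 ± 16.5, limma adjusted p = 2.87e-11), the metalloproteinase Mmp27 (42.3 ± 0.374 to 285 ± 17.9), the complement factor Cfb (9.42 ± 9.98 to 118 ± 28.4) and Ifit1bl1 (54.5 ± 11.8 to 223 ± 28.9). Cfb shares 75.5% and Ifit1bl1 19.3% of their 31-base words with other genes, so their counts are uncertain, and Cfb was listed at 0 in 1 control library. Of the glucocorticoid response genes, Fkbp5 fell by 1.13 on the log2 scale and Tsc22d3 rose by 0.72 on the log2 scale. Tnf rose by 0.18 (limma adjusted p = 0.0274, range 0.0134 to 0.121 over the alternatives, losing the call in 7 of 20), and Il6 was listed at 0 in all 6 vehicle libraries.

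Over all genes, 1132 were higher and 1298 lower of 12061 in vehicle by limma, against 1310 and 1474 in the authors' deposited columns, with 2370 calls in common and 0 in opposite directions. With plain library totals they were 969 and 1596, a median shift of -0.04. Of the other lists, secondary LPS response genes (7 higher, 2 lower of 23, over all genes and adjusted over the list alone) passed camera at adjusted p = 0.015, and at adjusted p = 0.16 with an estimated correlation. Macrophage identity genes (9 higher, 6 lower of 26, 10 and 6 adjusted over the list alone) passed at 0.049 and gave adjusted p = 0.318 with an estimated correlation. That call also ended with plain library totals (0.0567), the replicate number as a block (replicate block, 0.0638) and without the higher-numbered libraries (0.0947). Tyrobp (an immunoreceptor adaptor), Ints1 and Mfsd7a met the rule for the largest changes but switched between libraries, reading at or near 0 in a library of a group and far higher in another. Tyrobp read 2920, 2562 and 1248 with control siRNA and 218, 0 and 0 with Brg1 siRNA (limma adjusted p = 0.0303, range 0.00931 to 0.6 over the alternatives, losing the call in 10 of 19). Ints1 and Mfsd7a were listed at 0 in 1 control library each, with ranges of 0.000281 to 0.0524 and 0.000119 to 0.185.

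**Figure D2:**
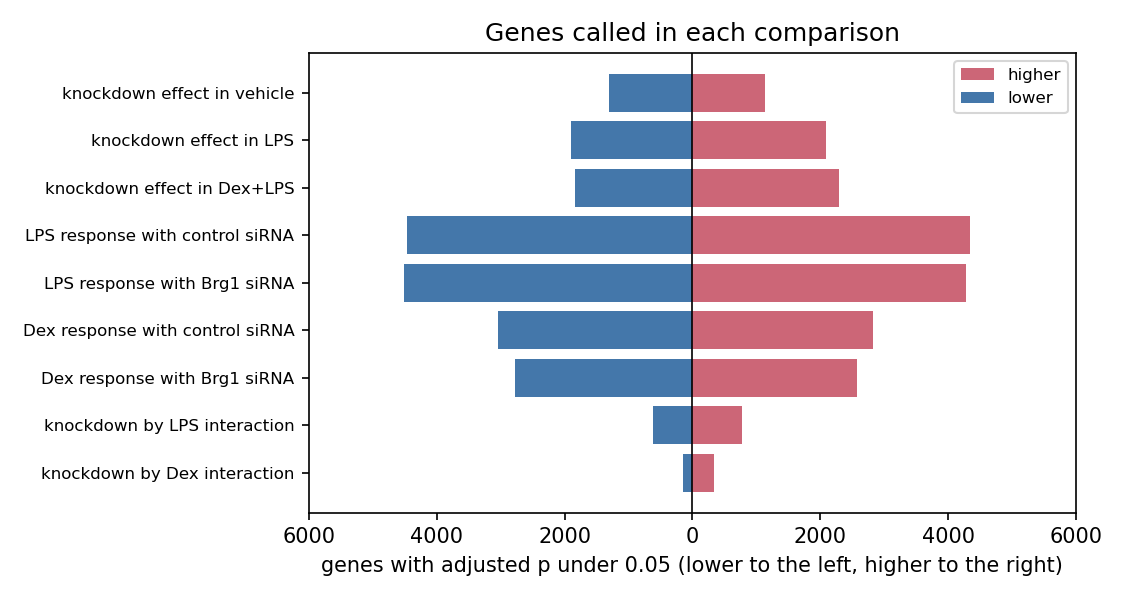
Genes called higher (to the right) and lower (to the left) at a limma adjusted p under 0.05 in each of the 9 comparisons, out of 12061 tested. The knockdown calls 2430 genes in vehicle, 3995 in LPS and 4131 in Dex+LPS, and with plain library totals the balance of higher and lower moves as the text gives.

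Under LPS, the question is how Brg1 knockdown alters the inflammatory state. Primary response genes, which LPS induces without new protein synthesis, were higher in 16 of 28 and lower in 1 (the same adjusted over the list alone). Tnf went from 107695 ± 3415 (SD, n = 3) to 203916 ± 8333 (SD, n = 3), the costimulatory ligand Tnfsf9 from 2979 ± 141 to 9679 ± 524 and the transcription factor Irf1 from 13948 ± 539.9 to 24085 ± 175. Secondary response genes split, with 6 higher and 7 lower of 23 (the same adjusted over the list alone). The growth factor Csf2 rose from 601 ± 65.4 to 3243 ± 370.1 and Il12b from 10952 ± 1213 to 29591 ± 3950.0. Il6 fell from 16088 ± 691 to 8919.6 ± 1497, the prostaglandin synthase Ptges from 13088 ± 908 to 5235 ± 79.8 and the acute phase gene Hp from 138 ± 25.6 to 19.02 ± 3.28. Nos2, the inducible nitric oxide synthase, rose from 6327 ± 191 to 12456 ± 305. Il1b, at 177856 ± 11070.0 and 225011 ± 22050.0, did not pass the test (limma adjusted p = 0.22, range 0.0118 to 0.482, passing in 4 of 20 alternatives), nor did Ccl5 (0.217).

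Glycolysis genes were lower with Brg1 siRNA in LPS in 13 of 17 and higher in 1 (the same adjusted over the list alone). They were led by Pfkfb3, which makes the activator of phosphofructokinase (3510.4 ± 155 to 902 ± 19.4), Pgam1 (6949.6 ± 72.5 to 3538 ± 187) and the lactate exporter Slc16a3 (1734 ± 248 to 731 ± 62.5). Macrophage identity genes were higher in 15 of 26 and lower in 3 (17 and 3 adjusted over the list alone). The pore-forming protein gene Mpeg1 went from 58489.6 ± 3619 to 106138 ± 2068, lysozyme Lyz2 from 128812 ± 8949 to 227039 ± 7349 and the cathepsin Ctsd from 67560.0 ± 712 to 105988 ± 3173. Cell cycle genes were again lower, 24 of 38 with 1 higher (the same adjusted over the list alone), as Ccna2 (73.7 ± 17.97 to 22.5 ± 3.32). Cholesterol synthesis genes were lower in 9 of 25 and higher in 1 (10 and 1 adjusted over the list alone, 15 and 1 with plain library totals), with Acat2 going from 320.2 ± 11.8 to 135.5 ± 5.25. Interferon-stimulated genes were higher in 12 of 35 and lower in 2 (the same adjusted over the list alone), among them Irf7 (5907 ± 461 to 10506 ± 322). By camera of limma, adjusted p was 8.87e-07 for primary response (0.0086 with an estimated correlation). It was 1.49e-05 for macrophage identity (0.0403) and 3.41e-07 for cell cycle (0.0403). Glycolysis passed at 3.01e-07, cholesterol synthesis at 0.00892 and the interferon list at 0.00892, with adjusted p = 0.0987, 0.131 and 0.606 with an estimated correlation. The interferon list's call in LPS ended with plain library totals (camera adjusted p = 0.0611), where 6 members were higher and 2 lower and the mean went from 0.21 to 0.07.

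The largest rises in LPS were in N4bp2l1, Ndst1, Lrrc14b, E2f2, Lyl1 and Mmp27 (21.6 ± 2.09 to 171 ± 18.3), and the largest falls in Nup107, Fos, Ighm, Col4a1, Hp and Serpinb9b. The immediate early gene Fos fell from 446 ± 41.5 to 38.1 ± 14.5 (log2 fold change -3.57, SE 0.177, limma adjusted p = 1.18e-10) and the serpin Serpinb9b from 518 ± 52.2 to 74.8 ± 9.01. N4bp2l1 read 0, 34.7 and 0 with control siRNA against 63.6, 83.5 and 80.7, Ndst1 193, 259 and 0 against 681, 313 and 529.7, and Nup107 100.3, 106 and 105 against 0, 43.6 and 0. Over the limma, edgeR and DESeq2 alternatives their adjusted p ranged from 3e-15 to 0.0543, 0.00593 to 0.239 and 3.57e-14 to 0.0515, and those of Lyl1, listed at 0 in 1 control library, from 1.04e-11 to 0.112, Col4a1 from 0.000154 to 0.216, Il12b from 6.06e-13 to 0.3 and Nos2 from 2.3e-28 to 0.0867. Col4a1 lost the call in 9 of 19 alternatives and Ndst1 in 7. Nos2, Il12b and Col4a1 did not pass without the libraries of the higher number series. E2f2 rested on 3 reads with control siRNA, a ratio of 26.5 (95% counting interval 9.08 to 129). In all, limma called 2089 genes higher and 1906 lower (authors' columns 2104 and 1855, 3717 calls in common and 0 opposite), and 1334 and 2919 with plain library totals, under which the median gene shifts by -0.14.

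Primary response genes moved up with the knockdown in LPS by a mean log2 fold change of 0.48 ± 0.55 (SD over 28 genes) and secondary response genes by -0.05 ± 1.15 (SD over 23 genes, median 0.15, opposite in sign to the mean). The difference of 0.53 had a two-sided permutation p of 0.0344 across genes, which are not independent replicates, and 0.0873 after Benjamini-Hochberg adjustment over the 3 treatments. It thus did not pass the correction. In vehicle the difference was -0.09 (permutation p = 0.699) and in Dex+LPS 0.45 (permutation p = 0.0582).

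**Figure D3:**
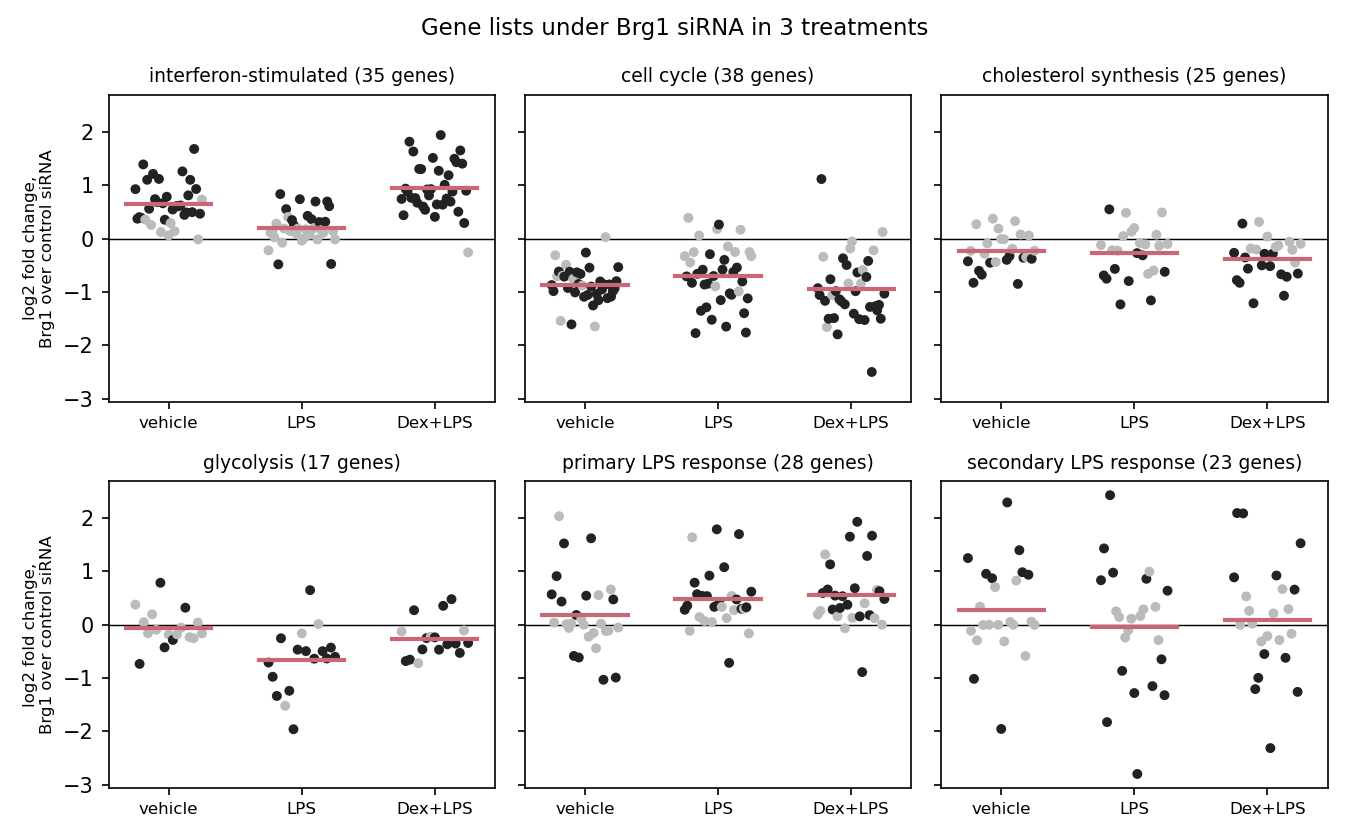
Log2 fold change of Brg1 against control siRNA for each tested gene (points) of 6 lists, in vehicle, LPS and Dex+LPS. Black points passed the limma test, grey points did not, and red lines are list means, which for interferon-stimulated genes are 0.65, 0.21 and 0.95.

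In macrophages given Dex with LPS, interferon-stimulated genes were higher with Brg1 siRNA in 34 of 35 and lower in 0 (the same adjusted over the list alone). Zbp1 went from 1239.6 ± 95.2 (SD, n = 4) to 3054 ± 52.0 (SD, n = 4), Irf7, a transcription factor of the interferon response, from 1858 ± 202 to 5739.6 ± 330.1 and the chemokine Cxcl10 from 1552 ± 172 to 5942 ± 460.4. Primary response genes were higher in 17 of 28 and lower in 1 (22 and 1 adjusted over the list alone), with Tnfsf9 at 2808 ± 330.1 and 8888 ± 163, Ccl4 at 7887 ± 569 and 17265 ± 703, and Irf1 at 6616 ± 238 and 10460.2 ± 424. Cell cycle genes were lower in 27 of 38 and higher in 1 (28 and 1 adjusted over the list alone), as Top2a (898 ± 67.9 to 396 ± 2.69) and Birc5 (132 ± 17.9 to 46.1 ± 5.17). Cholesterol synthesis genes were lower in 14 of 25 and higher in 1 (15 and 1 adjusted over the list alone, 21 and 0 with plain library totals), as Acat2 (466 ± 36.2 to 202 ± 31.5) and Sqle (1105 ± 22.3 to 747 ± 36.6). Macrophage identity genes were higher in 17 and lower in 3 of 26 (the same adjusted over the list alone), as Mpeg1 (54711 ± 3937 to 98829 ± 3996) and Ctsd (74336 ± 5635 to 115159 ± 1028). For these lists camera of limma returned adjusted p = 1.09e-24, 6.93e-08, 7.68e-13, 5.48e-06 and 1.63e-05. They became 0.0264, 0.00412, 0.00423, 0.0119 and 0.0264 with an estimated correlation. Glycolysis genes were lower in 10 of 17 and higher in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00489, and adjusted p = 0.435 with an estimated correlation).

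Glucocorticoid-induced genes divided under the knockdown in Dex+LPS, with 4 higher and 8 lower of 25. The counts were the same adjusted over the list alone, with camera adjusted p = 0.675. The efferocytosis receptor Mertk rose from 924 ± 78.9 to 1928 ± 90.9, the kinase Sgk1 from 1785 ± 103 to 2939 ± 303 and Tsc22d3 (GILZ) from 3220.1 ± 174 to 4786 ± 216. The transcription factor Klf9 fell from 667 ± 76.9 to 249 ± 25.7 and the chaperone Fkbp5 from 6468 ± 513 to 4308 ± 150.3, while Dusp1 and Per1 did not pass (limma adjusted p = 0.217 and 0.872). Tnf (58737 ± 3930.0 to 85008 ± 2422), Il1b (9257 ± 1526 to 14808 ± 1739) and Il12b (968 ± 288 to 4036 ± 465) rose, and Il6 fell (7559 ± 900.5 to 3287 ± 502). Over the limma, edgeR and DESeq2 alternatives, the adjusted p of Il12b ranged from 5.46e-34 to 0.0726, losing the call in 1 of 22. Ccl5 and Nos2 did not pass (limma adjusted p = 0.0624 and 0.125), though Ccl5 passed in 2 of 22 alternatives (0.000894 to 0.328) and Nos2 in 7 (8.66e-11 to 0.243).

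The largest rises in Dex+LPS were in Tnfrsf26, Lilra6 (49.6% of its 31-base words shared), Mmp27, the mRNA decay factor Zfp36l1 (63.4 ± 9.28 to 448 ± 27.7), E2f2 and the purinergic receptor P2ry13 (95.2 ± 9.82 to 479 ± 38.3). The largest falls were in St3gal1, the immunoglobulin gene Ighm (101 ± 22.7 to 2.73 ± 1.21), Col4a1, Srgap3 (147 ± 30.7 to 14.6 ± 6.97), the gelatinase Mmp9 (126 ± 16.7 to 19.2 ± 4.52) and Lad1 (613 ± 85.5 to 104 ± 6.87). Tnfrsf26 was listed at 0 in the 4 control libraries and read 168, 175, 159 and 159.7 with Brg1 siRNA, at least 235-fold higher against a floor of 3 reads over the group (adjusted p range 5.14e-07 to 0.0735 over 21 limma, edgeR and DESeq2 alternatives, losing the call in 1). Tnfrsf26 is among the genes that switch within a group, so this rise is uncertain. St3gal1, a sialyltransferase, read 378, 2206, 842 and 213 with control siRNA and was listed at 0 in every other library of the series, at least 1140-fold lower with Brg1 siRNA. Limma called 2289 genes higher and 1842 lower (authors' columns 2334 and 1922, 3993 calls in common and 0 opposite), and 1653 and 2847 with plain library totals, a median shift of -0.10.

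Across the 3 treatments, 623 genes were higher and 554 lower with Brg1 siRNA in all 3, of 3185 and 3023 that were so in at least 1, and 222 were higher in a treatment and lower in another. Log2 fold changes correlated across 12061 genes, which are not independent replicates, with Pearson r = 0.35 between vehicle and LPS (jackknife SE 0.035), 0.434 between vehicle and Dex+LPS (SE 0.063) and 0.57 between LPS and Dex+LPS (SE 0.045). These 3 contrasts share no libraries. In vehicle and LPS, 707 genes were higher in both and 665 lower in both, where independent lists would give 196 and 205. LPS and Dex+LPS shared 1432 higher and 1186 lower, where independent lists would give 396.5 and 291.

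LPS alone, with control siRNA, induced all 28 primary and all 23 secondary response genes tested (the same adjusted over the list alone). Il6 and Shisa3 were listed at 0 in vehicle and rose to 16088 ± 691 (SD, n = 3) and 21191 ± 573, at least 19000-fold and 25000-fold over a floor of 3 reads. Il1b went from 19.9 ± 6.08 to 177856 ± 11070.0, Ptgs2, the inducible cyclooxygenase, from 9.33 ± 1.10 to 156531 ± 5600.0, Tnf from 555 ± 28.4 to 107695 ± 3415, Ccl5 from 57.6 ± 5.96 to 37449 ± 1539 and Nos2 from 5.32 ± 3.45 to 6327 ± 191. Interferon-stimulated genes rose in 33 of 35 (34 adjusted over the list alone) with none lower (29 higher and 2 lower with plain library totals), as Cxcl10 (38.8 ± 5.65 to 17292 ± 1139), Gbp2 and Gbp3. MHC class II and costimulation genes rose in 8 of 10 (the same adjusted over the list alone), led by Cd40 (77.4 ± 8.24 to 36665 ± 2757) and H2-Ab1 (654 ± 71.0 to 2685 ± 242). Cholesterol synthesis genes rose in 19 and fell in 3 of 25 (20 and 3 adjusted over the list alone), and in 15 and 7 with plain library totals. Glycolysis genes rose in 13 and fell in 1 of 17 (the same adjusted over the list alone), and in 7 and 3 with plain library totals, with Slc2a1 at 415 ± 18.01 and 3066 ± 256.3.

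Cell cycle genes fell with LPS in 34 of 38 and rose in 2 (the same adjusted over the list alone). Mcm6 went from 1317 ± 82.5 to 211 ± 9.42 and Kif11 from 536 ± 50.8 to 60.2 ± 8.33. Against them stood Mki67, which marks cycling cells and rose from 1344 ± 133 to 6932 ± 666, and the cyclin gene Ccne1, picked after its values were seen, which rose from 96.1 ± 15.4 to 924 ± 46.6. Macrophage identity genes fell in 19 and rose in 5 of 26 (19 and 6 adjusted over the list alone), with the LPS coreceptor Cd14 rising from 3944 ± 309 to 44639 ± 4159. With control siRNA camera of limma gave adjusted p = 7.9e-20, 3.45e-15, 1.66e-08, 0.000516 and 0.00167 for primary, secondary, cell cycle, cholesterol and MHC class II lists. They became 2.06e-05, 0.000359, 0.0182, 0.0367 and 0.0325 with an estimated correlation. The interferon, glycolysis and macrophage identity lists passed at 1.36e-14, 0.00103 and 0.0108. They had adjusted p = 0.0877, 0.19 and 0.15 with an estimated correlation. The largest falls were in Tyrobp, listed at 0 in all 6 LPS libraries and at least 2010-fold lower than in control vehicle libraries, and in Zfp395, Cnr2 (742 ± 21.5 to 4.06 ± 2.69), Rasgrp3 (1169 ± 29.6 to 6.30 ± 1.03), N4bp2l1 and Klc4. Tyrobp, N4bp2l1 and Klc4 are among the genes that switch within a group, so their falls are uncertain. Klc4 read 0, 0 and 25.7 in LPS, with an adjusted p range of 0.000186 to 0.0637 over the limma, edgeR and DESeq2 alternatives, and Zfp395 rested on 3 reads in LPS, a ratio of 305 (105 to 1490).

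By limma 4341 genes were higher and 4464 lower with LPS and control siRNA (authors' columns 4437 and 4542, 8621 calls in common and 0 opposite), and 2434 and 6850 with plain library totals, a median shift of -0.58. Library totals of normalized counts differed with treatment, at 11.97 to 12.01 M in control vehicle and 17.76 to 18.14 M in control LPS libraries. Smarca4 itself rose with LPS by 0.90 on the log2 scale with control siRNA. Dusp1, a phosphatase of the MAP kinases, rose by 0.52 (limma adjusted p = 0.00208) and stood at -0.06 with plain library totals (limma adjusted p = 0.666, range 4e-05 to 0.666 over the alternatives).

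With Brg1 siRNA, LPS induced 27 of 28 primary response genes (28 adjusted over the list alone) and all 23 secondary response genes. Ptgs2 went from 9.44 ± 0.699 (SD, n = 3) to 189931 ± 19340.0 (SD, n = 3), Il12b from 1.12 ± 1.31 to 29591 ± 3950.0, Il1b from 16.9 ± 5.69 to 225011 ± 22050.0 and Il1a from 7.01 ± 0.738 to 86936 ± 11770.0, and Il6 rose at least 11000-fold over a floor of 3 reads. Alternative activation genes rose in 8 and fell in 2 of 12 (the same adjusted over the list alone), as the chemokines Ccl22 (12.4 ± 2.16 to 15089 ± 2321) and Ccl17, listed at 0 in vehicle and at least 285-fold higher, and the transglutaminase Tgm2 (2149 ± 53.6 to 9984 ± 319.5). Interferon-stimulated genes rose in 30 of 35 with none lower (the same adjusted over the list alone, but 27 higher and 5 lower with plain library totals), as Cxcl10 (43.2 ± 9.97 to 23186 ± 729) and Gbp3 (470.0 ± 36.3 to 14918 ± 1077). Cell cycle genes fell in 33 and rose in 2 of 38, MHC class II genes rose in 8 of 10, and cholesterol synthesis genes rose in 17 and fell in 3 of 25 (14 and 8 with plain library totals), each the same adjusted over the list alone. By the camera test of limma, adjusted p was 4.95e-20 and 2.6e-14 for the response lists, 1.26e-07 for cell cycle and 0.00117 for MHC class II, all kept with an estimated correlation. The interferon, cholesterol and alternative activation lists passed at 6.29e-12, 0.00117 and 0.0328. They had adjusted p = 0.138, 0.0545 and 0.061 with an estimated correlation. Falls were led by Klc4 and Mknk2, listed at 0 in the LPS libraries and at least 516-fold and 343-fold lower, then Zfp395, Get1, Cnr2 and Rfc1. Klc4, Mknk2, Get1 and Rfc1 are among the genes that switch within a group, the first at 0 in 11 and Mknk2 in 9 of the 20 libraries, so these falls are uncertain. Rfc1 had an adjusted p range of 0.00016 to 0.0742 over the limma, edgeR and DESeq2 alternatives, losing the call in 3 of 19. In all 4275 genes were higher and 4511 lower (authors' columns 4373 and 4510, 8558 calls in common and 0 opposite). With plain library totals they were 2219 and 7328, a median shift of -0.68. Under that scaling the rise of Smarca4 by 0.74 (8.58e-14 to 0.528) and of Dusp1 by 0.78 (4.34e-08 to 0.468) did not pass, each range being of adjusted p over the limma, edgeR and DESeq2 alternatives.

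**Figure D4:**
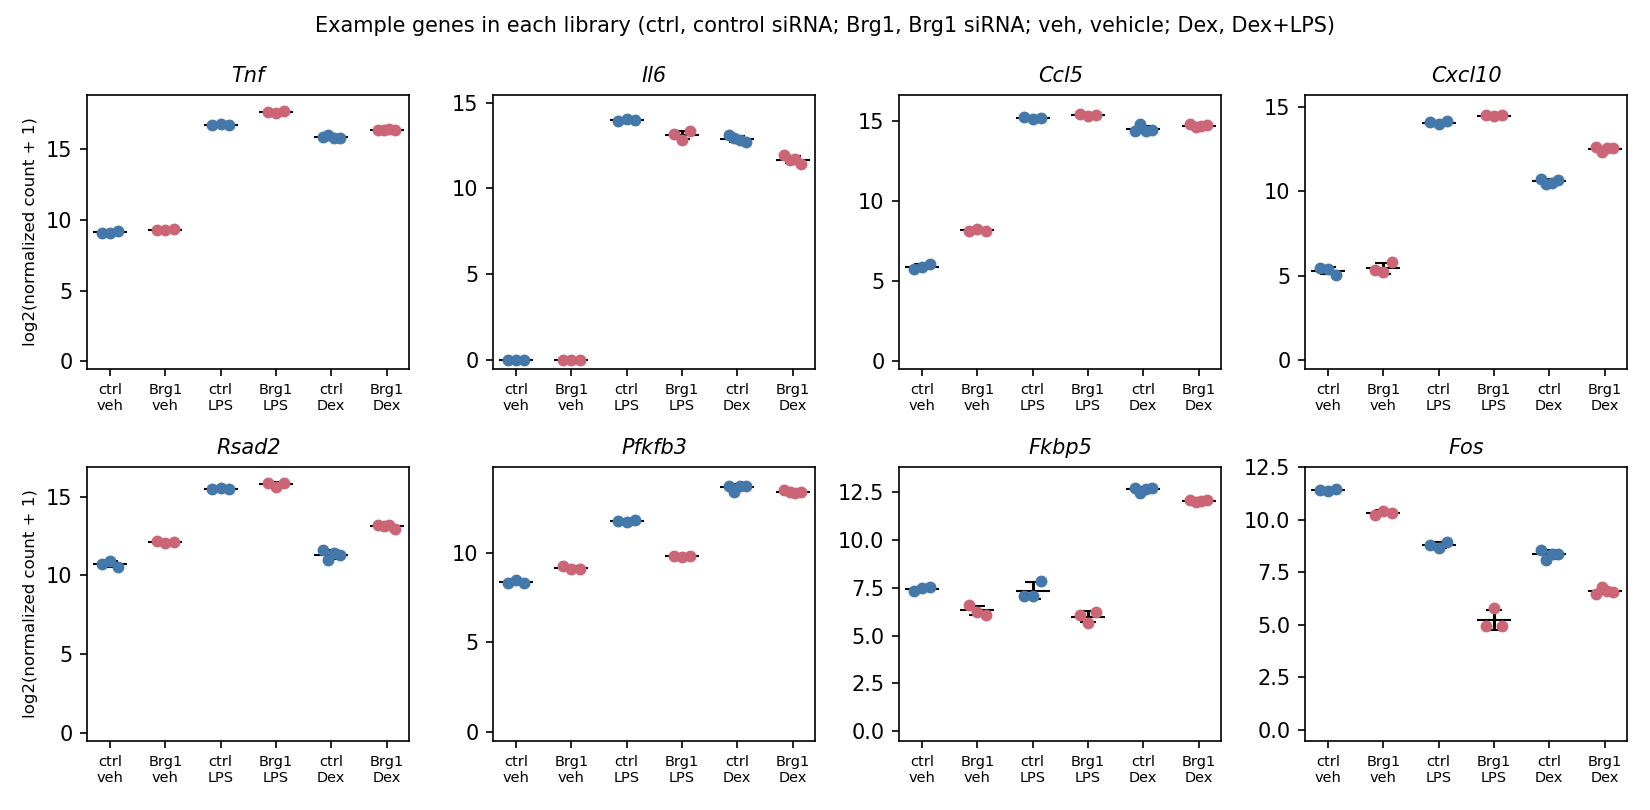
Log2(normalized count + 1) per library (points) with mean and SD for 8 genes in the 6 groups. Tnf and Il6 are induced by LPS in either siRNA arm, Rsad2 and Cxcl10 are lower with Dex, and Fkbp5 rises with Dex.

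Dex given with LPS, with control siRNA, lowered all 35 interferon-stimulated genes tested and 24 of 28 primary response genes with none higher (each the same adjusted over the list alone). With plain library totals 19 primary response genes were lower and 2 higher. Rsad2 went from 46363 ± 569.8 (SD, n = 3) to 2593 ± 482 (SD, n = 4), Cmpk2 from 14860.4 ± 489.5 to 982 ± 87.2, Ptgs2 from 156531 ± 5600.0 to 8407 ± 1668 and Ccl4 from 30373 ± 618 to 7887 ± 569. Il1b fell from 177856 ± 11070.0 to 9257 ± 1526, Tnf from 107695 ± 3415 to 58737 ± 3930.0, Il6 from 16088 ± 691 to 7559 ± 900.5 and Csf2 from 601 ± 65.4 to 6.73 ± 1.61. Secondary response genes were lower in 16 and higher in 4 of 23 (the same adjusted over the list alone). Glucocorticoid-induced genes rose in 14 and fell in 5 of 25 (14 and 6 adjusted over the list alone), led by Tsc22d3 (32.6 ± 7.64 to 3220.1 ± 174), Fkbp5 (167 ± 54.6 to 6468 ± 513) and the clock gene Per1 (128 ± 33.5 to 1236 ± 176), with Dusp1 going from 1676 ± 202 to 6289 ± 789.6.

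Cell cycle genes rose with Dex in 29 and fell in 2 of 38 (the same adjusted over the list alone), with Nusap1 going from 69.2 ± 6.71 to 233 ± 21.8 and Ccne1 from 924 ± 46.6 to 226 ± 49.8. Glycolysis genes fell in 13 and rose in 2 of 17 (the same adjusted over the list alone), with Pfkp going from 3029 ± 179.5 to 1102 ± 94.97 against Pfkfb3, which rose from 3510.4 ± 155 to 13032 ± 1393. Other large rises were the Wnt receptor Fzd4 (3 reads in LPS, a ratio of 242 with a counting interval of 82.9 to 1180), Prss16 (5.23 ± 3.28 to 588 ± 80.2) and Lifr (2.59 ± 0.535 to 237 ± 12.0). Other large falls were the collagenase Mmp13 (21127 ± 1790.0 to 399 ± 61.8), Inhba, Serpinb2 (1363 ± 85.5 to 29.3 ± 4.55) and Ccl7. For Dex, camera of limma gave adjusted p = 1.02e-30 for the interferon list, 1.72e-12 for primary and 8.59e-05 for secondary response. It was 0.000487 for glucocorticoid-induced and 3.15e-07 for cell cycle genes, all kept with an estimated correlation. Glycolysis, macrophage identity (5 higher, 13 lower of 26), MHC class II (1 higher, 6 lower of 10) and dendritic cell markers (0 higher, 4 lower of 5), all alike adjusted over the list alone, passed at 0.000514, 0.0291, 0.0161 and 0.0291. They had adjusted p = 0.208, 0.208, 0.0675 and 0.0675 with an estimated correlation. With plain library totals the macrophage identity list turned to 9 higher and 6 lower and its call ended.

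Limma called 2827 genes higher and 3041 lower with Dex and control siRNA (authors' columns 2740 and 3059, 5596 calls in common and 0 opposite), and 5269 and 1647 with plain library totals, a median shift of 0.30. Of 4341 genes that LPS induced with control siRNA, 2177 (50.1%) were lower with Dex (980 of 2434 with plain library totals), where lists of independent genes would share 1095. In 20 data sets simulated with unchanged genes and the shared LPS libraries the mean was 0. Hardly any gene is called where none changes, so that 0 cannot serve as a comparison for the count. The covariance of the LPS and Dex log2 fold changes across genes was -0.885, beside -0.0793 in the simulated data. The Pearson correlation across genes, -0.493, was no stronger than the simulated -0.556. In a test added after the data were seen, the 3 LPS libraries were split so that the LPS and the Dex response shared none. Over the 6 splits 1502 to 1857 LPS-induced genes were lower with Dex, where independent lists would share 715 to 868.2. The correlation ran from -0.399 to -0.431, with means of -0.005 to 0.009 in data simulated with unchanged genes. Unchanged genes with no shared library give about 0 by construction. The simulated means thus show only that the split removes the correlation built in by shared libraries.

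With Brg1 siRNA, Dex also lowered all 35 interferon-stimulated genes (the same adjusted over the list alone), with Rsad2 going from 56427 ± 5182 (SD, n = 3) to 9023 ± 686 (SD, n = 4) and Cmpk2 from 15127 ± 1433 to 1807 ± 160.3. Primary response genes were lower in 25 and higher in 0 of 28 (26 and 0 adjusted over the list alone, 19 and 1 with plain library totals), and secondary response genes lower in 17 and higher in 3 of 23 (the same adjusted over the list alone). Il1b (225011 ± 22050.0 to 14808 ± 1739), Tnf (203916 ± 8333 to 85008 ± 2422) and Csf2 (3243 ± 370.1 to 31.5 ± 2.79) were among them. Glucocorticoid-induced genes rose in 15 and fell in 5 of 25 (15 and 6 adjusted over the list alone), led by Fkbp5 (63.3 ± 12.3 to 4308 ± 150.3), Tsc22d3 (101 ± 13.0 to 4786 ± 216) and the metallothionein Mt2 (171 ± 10.9 to 5102 ± 1416). Cell cycle genes rose in 24 and fell in 3 of 38 (26 and 3 adjusted over the list alone). MHC class II genes fell in 7 and rose in 0 of 10 (7 and 1 adjusted over the list alone), alternative activation genes fell in 7 and rose in 2 of 12, and dendritic cell markers fell in 3 and rose in 0 of 5, the last 2 the same adjusted over the list alone. The camera adjusted p of limma ran from 3.68e-26 for the interferon list to 0.0135 for alternative activation and dendritic markers, and all 8 of these lists kept their call with an estimated correlation. Glycolysis (0.0291) and macrophage identity (0.0135) gave adjusted p = 0.537 and 0.171 with an estimated correlation, and both calls ended with plain library totals (0.0725 and 0.246). There glycolysis genes turned to 6 higher and 6 lower, with a mean of 0.11, and macrophage identity genes to 9 and 6, with a mean of 0.06.

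By limma 2575 genes were higher and 2777 lower with Dex and Brg1 siRNA (authors' columns 2472 and 2812, 5090 calls in common and 0 opposite), and 5388 and 1232 with plain library totals, a median shift of 0.33. Of 4275 LPS-induced genes, 2057 (48.1%) were lower with Dex (770 of 2219 with plain library totals, 984 for independent lists). The simulated mean of 0.05 again cannot serve as a comparison, since hardly any unchanged gene is called. The covariance was -0.762 beside -0.0771 in the simulated data. Here too the correlation (-0.481) was no stronger than the simulated (-0.549). With no LPS library shared, 1300.0 to 1813 were lower over the 6 splits (639.4 to 782.8 for independent lists), and the correlation ran from -0.313 to -0.405. The simulated means were -0.021 to -0.008, again near 0 by construction. The largest rises besides those named were in Fzd4, Prss16 and Tns1 (227 ± 46.8 to 7149 ± 559), and large falls in Cd300lb (at 0 in 3 of the 4 Dex+LPS libraries), Serpinb2, Mmp13 and Cish (3177 ± 368 to 168 ± 19.6). The Dex response of Smarca4, -0.38, did not pass with plain library totals (limma adjusted p = 0.686, range 3.28e-05 to 0.686).

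The interaction of knockdown and LPS tests which genes respond to Brg1 siRNA differently in LPS and in vehicle. Interferon-stimulated genes, higher in vehicle with the knockdown, had a negative interaction in 14 of 35 and a positive in 0 (18 and 0 adjusted over the list alone, 9 without the higher-numbered libraries and 19 with plain library totals), as Rsad2 (interaction -1.11 on the log2 scale) and Zbp1 (-0.66). Primary response genes had a positive interaction in 12 and a negative in 2 of 28 (the same adjusted over the list alone), as Tnfsf9 (1.82), Nfkbiz (1.51) and Tnf (0.74, SE 0.08, limma adjusted p = 6.99e-06). Secondary response genes had a negative interaction in 9 and a positive in 1 of 23 (11 and 4 adjusted over the list alone), as Ccl5 (-2.13), Saa3 (-2.55) and Hp (-2.48). Glycolysis genes had a negative interaction in 7 and a positive in 1 of 17 (10 and 1 adjusted over the list alone), as Pfkfb3 (-2.75, SE 0.115, limma adjusted p = 5.86e-11). Camera returned limma-based adjusted p = 1.39e-10, 0.000216, 0.000524 and 1.91e-06 for these lists. They had adjusted p = 0.188, 0.0572, 0.0893 and 0.148 with an estimated correlation. In all 771 genes were higher and 609 lower, and 567 and 921 with plain library totals, a median shift of -0.10. Il6, listed at 0 in vehicle, gave a limma adjusted p of 0.00359 with a range of 0.000215 to 1 over the alternatives, and N4bp2l1, Nup107 and Ints1, which switch between libraries, ranged over 3.63e-13 to 0.099, 2.08e-11 to 0.0981 and 0.018 to 0.131. Il6 lost the call in 4 of 25 alternatives, N4bp2l1 in 2, Nup107 in 15 and Ints1 in 13 of 24, so the last 2 failed in most.

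The interaction of knockdown and Dex tests the same between Dex+LPS and LPS. Interferon-stimulated genes had a positive interaction in 29 of 35 and a negative in 0 (32 and 0 adjusted over the list alone), as Rsad2 (1.53, SE 0.169, limma adjusted p = 3.97e-05), Cxcl10 (1.51) and Oasl1 (1.34). Dex took Rsad2 to 2593 ± 482 with control siRNA and to 9023 ± 686 with Brg1 siRNA. Camera of limma gave adjusted p = 1.1e-38 and 0.0264 with an estimated correlation, and 18 of the 35 were called without the higher-numbered libraries. Glycolysis genes had a positive interaction in 4 and a negative in 0 of 17 (8 and 0 adjusted over the list alone), led by Pfkfb3 (1.71), Pfkp (0.53) and Hk1 (0.47), with camera adjusted p = 1.71e-06 and adjusted p = 0.29 with an estimated correlation. Other genes with a positive interaction were Fos, Rnd1, Glipr2 and Mt2, and with a negative Coq8a, Fabp4, Plxna2 and Susd2. For Fos it reflects a smaller fall with the knockdown, from 328 ± 45.4 to 96.4 ± 9.40 in Dex+LPS. By limma 332 genes were higher and 147 lower (390.0 and 115 with plain library totals), 479 in all, which became 300.0 without the higher-numbered libraries and 722 with DESeq2.

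Markers of other cell types were mostly low or left out by the filter. Of the neutrophil markers, 9 were tested and 1 was lower with Brg1 siRNA in vehicle and in LPS (in vehicle 2 higher and 1 lower adjusted over the list alone, in LPS 0 and 1), Mmp9 each time. In Dex+LPS 1 was higher and 1 lower, the same adjusted over the list alone. Of the dendritic cell markers, 5 were tested and 1 was lower in each treatment, the same adjusted over the list alone. It was the integrin gene Itgax, picked after its values were seen, from 1869 ± 40.1 to 421 ± 18.02 in vehicle. Of the T and NK cell markers, 3 were tested, with Cd4 higher in LPS and Dex+LPS, Klrb1c higher in Dex+LPS and 0 called in vehicle over all genes (1 higher and 1 lower adjusted over the list alone). Single tested members stood for mast cells (Kit, -0.003 in vehicle and 3.18 in Dex+LPS, where it was called), B cells (Cd79b, -0.79 in vehicle) and fibroblasts (Pdgfrb, -0.04 in vehicle and 8.27 with LPS), the calls in these comparisons alike adjusted over the list alone. The 9 erythroid markers had 2 in the table and 0 tested. As signs of RNA quality, 1 of 13 mitochondrial transcripts was lower with the knockdown in vehicle (0 adjusted over the list alone, mean -0.40, camera adjusted p = 0.0265, and adjusted p = 0.506 with an estimated correlation). Non-polyadenylated and nuclear RNA had 2 of 5 lower, H1f2 and Neat1 (the same adjusted over the list alone, with the selection of polyadenylated RNA left open by the labels, camera adjusted p = 0.0446, and adjusted p = 0.134 with an estimated correlation). The latter call also ended with plain library totals (0.0559) and without the higher-numbered libraries (0.0508). The 4 libraries of the higher number series in the labels (control siRNA LPS replicate 3 and Dex+LPS replicate 4, Brg1 siRNA LPS replicate 2 and Dex+LPS replicate 4) had the lowest mitochondrial percent of their groups (1.01%, 1.25%, 0.856% and 0.969%), and their deviations from the group means correlated at 0.243 to 0.591 across 9770 genes.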

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

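The breakdown of the other splits for the 2 interactions was chosen only after their result was seen. Plain library totals were also chosen only after the data were seen, though what their test here would show was written before it was run. The other tests of this part were planned before.

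The knockdown effect differed between LPS and vehicle by the interaction test of limma, in 1380 genes. Among primary response genes (mean interaction 0.29 on the log2 scale), those named were Tnfsf9 (1.82), Nfkbiz (1.51), Nfkbie (1.12) and Tnf (0.74). Secondary response genes (mean -0.32) held Saa3 (-2.55), Hp (-2.48), Ccl5 (-2.13) and Il6 (-0.86). Interferon-stimulated genes (mean -0.44) included Rsad2 (-1.11), Gbp2 (-0.77) and Zbp1 (-0.66), and glycolysis genes (mean -0.60) Pfkfb3 (-2.75), Pfkl (-1.38) and Slc16a3 (-1.14). Alternative activation genes (mean 0.35) included Egr2 (2.72) and Ccl22 (1.63, adjusted p range 1.08e-05 to 0.106 over the 25 limma, edgeR and DESeq2 alternatives, losing the call in 1), and macrophage identity genes had a mean of 0.20. Tsc22d3 stood at 0.89. Under the rule for named genes, the largest positive values were those of N4bp2l1 (4.53), Sema6d (4.06), Cass4 (3.75), E2f2 (3.29), Mycl (3.25) and Ccr3 (3.06). The largest negative were those of Cfb (-4.82), Nup107 (-4.26), Ints1 (-3.93), Rnd1 (-3.22), Hdc (-3.05) and Mt2 (-3.04). Nup107 lost its call in 15 of 24 alternatives (adjusted p 2.08e-11 to 0.0981) and Ints1 in 13 (0.018 to 0.131), so neither is firm. N4bp2l1 lost it in 2 (3.63e-13 to 0.099), and Il6, at 0 in vehicle, in 4 of 25 (0.000215 to 1). By camera the alternative activation list passed at adjusted p = 0.0162 (5 positive and 1 negative of 12, the same adjusted over the list alone), with adjusted p = 0.0893 with an estimated correlation. The macrophage identity list passed at 0.00997 (5 positive and 2 negative of 26, 8 and 2 adjusted over the list alone), with adjusted p = 0.188 with an estimated correlation.

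Between Dex+LPS and LPS the knockdown effect differed in 479 genes. Interferon-stimulated genes (mean 0.75) were raised further by the knockdown in Dex+LPS, with Rsad2 at 1.53, Cxcl10 at 1.51 and Oasl1 at 1.34, and glycolysis genes (mean 0.40) held Pfkfb3 (1.71), Pfkp (0.53) and Hk1 (0.47). The camera test also called cell cycle (mean -0.25, adjusted p = 0.0319) and oxidative phosphorylation (mean -0.16, adjusted p = 0.0366). In both, limma called 0 single genes over all genes and adjusted over the list alone, and camera gave adjusted p = 0.415 and 0.618 with an estimated correlation. The cell cycle call also ended without the higher-numbered libraries (adjusted p = 0.252, mean -0.13) and the other with plain library totals (adjusted p = 0.077, mean -0.12). Under the rule for named genes, the largest positive values besides that of Pfkfb3 were Fos (1.82), Zbtb21 (1.77), Rnd1 (1.70), Glipr2 (1.67) and Mt2 (1.65). The largest negative were St3gal1 (-9.28), Coq8a (-2.40), Fabp4 (-1.81), Plxna2 (-1.41), Gpr155 (-1.26) and Susd2 (-1.20). Tsc22d3 stood at -1.05 and Tnf at -0.39. Over the 27 limma, edgeR and DESeq2 alternatives, Gpr155 lost its call in 12 (adjusted p 0.0102 to 0.123), St3gal1 in 4 (5.73e-07 to 1), Susd2 in 2 (9.92e-08 to 0.447), Zbtb21 in 2 (0.000971 to 0.0949) and Coq8a in 1 (4.13e-05 to 0.0602). St3gal1 reads 0 in 3 of the 4 groups behind this value, so its size depends on the pseudocount.

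Interferon-stimulated genes such as Rsad2 and Zbp1 were higher with Brg1 siRNA in vehicle (27 of 35) and in Dex+LPS (34 of 35). With plain library totals in place of size factors, 26 members were called higher in vehicle, where they shift the median gene by -0.04, against the pattern. In Dex+LPS, with a shift of -0.10, 33 were called higher. The choice between these scalings thus does not make the pattern. Beside a list mean of 0.65 in vehicle, so small a shift could hardly have removed the calls, so the count is a weak test of the size factors as cause. Both siRNA arms of Dex+LPS held 1 higher-numbered library each, and vehicle had none. A shift common to these libraries would cancel, so the 34 members called higher in Dex+LPS without them do not test them as the cause. An effect of the siRNA product on interferon sensing stays open and untested, since each arm had 1 product, and so does a role of Brg1 at these genes. A biological reading therefore remains a hypothesis.

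For the LPS interaction, 8 of 100 splits of the samples, the real included, called as many genes as the real 1380 (highest other 2106), so this count does not exclude chance. For the Dex interaction 9 of 100 did (real 479, highest other 3264), so chance is not excluded there either. The highest other split called several times the real count for the Dex interaction only. All 7 and all 8 other splits as large exchanged a clearly larger share of the siRNA labels in a treatment than in the other. Such splits carry part of the knockdown effect itself into the interaction. A further 50 and 22 splits of that kind were not as large. Among the remaining 42 and 69 splits the highest counts were 2 and 159, with 0 as large in either.

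Of 144 groups of 4 samples tested, all of Dex+LPS, some were of reads or mitochondrial percent and the rest of genes. Chance gives 7.2 of the 144 with a library far from the other 3 (by Dixon's ratio of gap to range). Among genes there were 11, besides the mitochondrial percent given last. With control siRNA these were Ccl5 (ratio 0.8523) and Fabp4 (0.968), higher in replicate 2, Pfkfb3 (0.9734), lower in replicate 2, Mmp9 (0.8767), lower in replicate 3, and Zbp1 (0.9152), higher in replicate 1. With Brg1 siRNA they were Mt2 (0.8617), Per1 (0.8616) and Cd300lb (ratio 1), higher in replicate 4, Ighm (0.9099), lower in replicate 4, Cxcl10 (0.8295), lower in replicate 2, and Glipr2 (0.8784), lower in replicate 3. The mitochondrial percent of Brg1 siRNA, Dex+LPS replicate 4 also stood apart (0.8697), at 0.969%.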

How the results depend on the processing

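Plain library totals (planned only for the Smarca4 level), the authors' columns, the edgeR test with TMM factors and the run without switching genes were chosen only after the data were seen. For single genes, direction was compared only where the main test or the alternative called the gene. Of 6159 single-gene values under alternatives, 6018 kept the side of the threshold, 108 lost the call, 32 gained it and 1 reversed. That is Dusp1, LPS response with control siRNA, at -0.063 with plain library totals (limma adjusted p = 0.666, range 4e-05 to 0.666), where the scaling shifts all genes. Requiring an absolute log2 fold change of at least 1 left 459, 911 and 793 genes for the knockdown in vehicle, LPS and Dex+LPS. It left 4896 and 4947 for LPS with control and Brg1 siRNA, 1878 and 1506 for Dex, and 408 and 102 for the LPS and Dex interactions. An adjusted p under 0.01 left 1521 for the knockdown in vehicle, 751 for the LPS interaction and 209 for the Dex interaction. The Dex interaction, 479 genes, gave 722 with DESeq2, 730.0 with the library series as a term, 300.0 without the higher-numbered libraries and 319 with only the groups compared, and the cause was not tested. With the replicate number as a block (replicate block) the knockdown in vehicle gave 2646 genes, though replicate numbers do not pair these samples. The mitochondrial transcripts list, not called for the knockdown in Dex+LPS (camera adjusted p = 0.0746), was called with that block (0.0311) and without the higher-numbered libraries (0.00226). Of 171 list tests, 65 passed camera, 32 with an estimated correlation and 114 with fry, which asks a different question. The difference of primary against secondary LPS response genes under knockdown, 0.53, gave 0.471 without the higher-numbered libraries (permutation p = 0.0588). Over single libraries left out it ran from 0.455 (without Brg1 siRNA, LPS replicate 2, permutation p = 0.0689) to 0.578 (without Brg1 siRNA, LPS replicate 3, permutation p = 0.0214). The similarity of the knockdown effect, vehicle and LPS, was 0.35 and became 0.425 at a mean of at least 100, 0.425 by Spearman and 0.469 without switching genes, and 0.314 to 0.349 with single libraries left out. The similarity of the knockdown effect, vehicle and Dex+LPS, 0.434, became 0.533 at that mean and 0.526 without switching genes. The similarity of the knockdown effect, LPS and Dex+LPS, 0.57, became 0.683 at that mean, 0.644 by Spearman, 0.679 without switching genes, 0.494 without the higher-numbered libraries and 0.525 to 0.575 with single libraries left out. The LPS-induced genes lower with Dex, control siRNA, fell from 2177 to 558 at both stricter thresholds together and to 980 with plain library totals. The LPS-induced genes lower with Dex, Brg1 siRNA, went from 2057 to 409 and 770 in the same way. Alternatives for tables of the authors' comparisons alone were not run, and without switching genes the primary and secondary lists gave no value. Depth limits the calls on genes near 0 reads.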

Other observations

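The tests of low depth, of genes with at least 10% shared words and of the cell cycle level against the median gene were chosen only after the results were seen.

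Several stress and lipid genes moved with Brg1 siRNA in vehicle. Of the unfolded protein and ATF4 genes, 7 were lower and 1 higher of 21 (8 and 1 adjusted over the list alone), with the chaperone genes Calr (-0.56) and Hsp90b1 (-0.52) lower and Ddit3 (0.46) higher. By camera of limma the list passed at adjusted p = 0.0446, with adjusted p = 0.255 with an estimated correlation, and the call also ended without the higher-numbered libraries (0.0505). LXR targets were higher in 3 and lower in 5 of 12 (the same adjusted over the list alone, camera adjusted p = 0.325). The p53 targets were higher in 2 and lower in 4 of 19 (2 and 5 adjusted over the list alone, camera adjusted p = 0.325), with a mean of 0.02 and a median of -0.15, opposite in sign. MHC class II genes were higher in 3 and lower in 4 of 10, and alternative activation genes higher in 3 and lower in 4 of 12, each the same adjusted over the list alone. Oxidative phosphorylation genes were higher in 1 and lower in 1 of 30 (0 adjusted over the list alone). With LPS and control siRNA, p53 targets rose in 13 and fell in 4 of 19 (the same adjusted over the list alone). Camera gave adjusted p = 0.0291 for them, and adjusted p = 0.0574 with an estimated correlation. Cdkn1a (4.71) and Gdf15 (4.93) rose and Sesn1 (-4.22) fell, genes picked after their values were seen.

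Cell cycle genes such as Top2a and Mki67 were lower with Brg1 siRNA in vehicle, LPS and Dex+LPS. Size factors multiply all genes of a library alike. Apart from the pseudocount of 1, they thus leave the list's mean log2 level less the median of all tested genes unmoved. With Brg1 siRNA this level was lower by 0.842 in vehicle, 0.668 in LPS and 0.953 in Dex+LPS, with no overlap of the libraries. The weakest Brg1 minus control value, -0.668 in LPS, became -0.656 with plain library totals. The exact permutation p was 0.1, 0.1 and 0.0286, the first 2 being the smallest that 3 against 3 libraries can give. This argues against the size factors as cause. The higher-numbered libraries stood alike in both siRNA arms of LPS and of Dex+LPS, and vehicle had none. A shift common to these libraries would cancel, so the 28 members called lower in Dex+LPS without them do not test them as the cause. Fewer dividing cells and less of these transcripts per cell both stay open and were not tested.

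Within a group, 478 tested genes, among them Tyrobp and Ndst1, switched by 4 or more on the log2 scale between libraries, and 89 of them had a mean of at least 100. Low depth as the whole cause is argued against by 75.3% of them (360.0 genes) having their lowest library below counting error. The median share of 31-base words was 1.1% in these genes and 0.43% in matched genes, 0.67 points apart (permutation p = 1e-05, the smallest that the draws can give). That excess goes with reads shared between gene models, but so low a median argues against them as the general cause. For a part they remain a candidate explanation, since 29.1% of the switching genes, against 15% of matched genes, share at least 10% of their words (permutation p = 1e-05, again the smallest possible). In the 89 with a mean of at least 100, the medians were only 0.07 points apart, at 0.6% and 0.53% (permutation p = 0.398). Of those 89, 25.8% shared at least 10% of their words, against 11.7% of matched genes (permutation p = 0.00018). No biological explanation was tested.

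For the knockdown in Dex+LPS, 1 of 35 splits of the 8 libraries called as many genes as the real 4131, which is the real split itself (highest other 5). That is the smallest share that 35 splits can give, not corrected over the comparisons. It argues against chance without excluding it. The Dex responses with control and Brg1 siRNA also had only the real split as large, 1 of 35 each. Their real counts were 5868 and 5352 and the highest others 3898 and 3318, which argues against chance there too, again without excluding it. Those highest others set the 3 LPS libraries with Dex+LPS replicate 4 against the rest, close to a mirror of the real split. Groups of 3 against 3 allow only 10 splits, too few for a share under 0.05. Among those, the real split alone (1 of 10) gave the real value in each case. For the knockdown in vehicle it was 2430.0 with a highest other of 3, and for the knockdown in LPS 3995 and 6. For LPS with control siRNA it was 8805 and 0, and with Brg1 siRNA 8786 and 1.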
